A study of Mus musculus with 24 samples.

How the data were processed

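Mouse embryonic fibroblasts from 6 embryos of embryonic day 13.5, 3 wild type (WT) and 3 carrying 1 intact allele of Eif4e (Eif4e+/-, here heterozygous or Het), were profiled untransformed and after transformation with Ras and Myc, so that both states came from the same embryo. Per the labels' protocols, cells grew in medium with 10% serum and were harvested in exponential growth. Per the labels' protocols, total cellular RNA was taken directly, and polysomal RNA came from cytoplasmic extracts of cells treated with cycloheximide at 100 µg/ml, separated on a 10 to 50% sucrose gradient to isolate high molecular weight polysomes. RNA was amplified with the NuGEN Applause WT Amp Plus system and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. The 24 arrays formed 8 groups of 3, set by 2 genotypes, 2 states and 2 fractions.

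The deposited values were log2 RMA intensities made by the authors, per the submitters' processing notes and series description. The RMA version, the chip definition and the probe set filter were not given in the sources used here. Array means lay between 7.47 and 7.50 in total RNA and between 3.78 and 3.79 in polysomal RNA, so each fraction had its own common level and a difference between fractions had no absolute scale. All 25668 probe sets in the deposited table were read. In the platform annotation 20777 carried 1 gene symbol, 232 carried several and 4659 carried none; the last 2 classes were not analysed here. The symbols covered 19661 genes, and 564 of them had more than 1 probe set, of which the brightest over all 24 arrays was used. A gene was kept where its value exceeded the array's 40th percentile on at least 3 arrays, which left 14830 genes.

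Translational efficiency (TE) was taken as in the series description, log2 polysomal minus log2 total of the same culture, which gave 12 values per gene. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Genotype effects, written Het minus WT, came from a fit of 4 group means with 8 residual degrees of freedom. Transformation effects, written transformed minus untransformed, and the difference of the genotype effects between the states came from fits with embryo as a block and 4 residual degrees of freedom, because the labels match both states by embryo. For the cells of the same embryo, deviations from the group means correlated at 0.125, 0.064 and -0.058 for the WT embryos and 0.045, 0.219 and 0.209 for the heterozygous embryos in total RNA. In TE they were -0.19, 0.01 and -0.413 for WT and 0.097, 0.097 and 0.05 for heterozygous embryos, and in polysomal RNA -0.119, -0.052 and -0.438 for WT and 0.062, 0.019 and 0.053 for heterozygous embryos. An embryo's states correlated best with each other in 3 of 3 heterozygous embryos in total RNA, but in 0 or 1 of 3 in each other case, so outside total RNA of heterozygous cells the block rests on the labels. Comparisons of group values, 3 cultures against 3, used exact two-sided permutation tests, which cannot go below 0.1.

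Gene lists were fixed before the data were examined. They covered eIF4F and its regulators, other initiation factors, cytosolic ribosomal proteins, other TOP mRNAs (with a terminal oligopyrimidine start), mRNAs reported as eIF4E-sensitive, redox and antioxidant genes, nuclear-encoded oxidative phosphorylation subunits, mitochondrial ribosomal proteins, MYC ribosome biogenesis targets, RAS-ERK output, S phase, G2 and mitosis, extracellular matrix, contractile genes, ATF4 stress response, cholesterol synthesis, interferon response and p53 targets. Further lists held replication-dependent histones, nuclear noncoding RNAs, sex-linked genes and markers of fibroblasts, endothelium, leukocytes, neural cells, epithelium, muscle, cartilage and adipocytes. Genes of the mitochondrial genome were also listed, but 0 of 28 were measured. Of 79 ribosomal proteins 22 were measured (27.8%). The remaining 29 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. In fry, the directional p tests whether the genes of a list move on balance in a common direction, and the mixed p whether they change in either direction; neither sets a list against other genes. No list call at the preset correlation held with an estimated correlation in any of the 12 comparisons.

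Named genes followed a rule fixed before the data were examined. Per comparison, these were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (in paired fits, whose embryos all moved the same way). Where fewer than 5 passed in a direction, the 5 smallest p-values in that direction were taken as values that did not pass. The 4 leading members of each called list, Eif4e and the eIF4F members were added. The fitting steps were tested on simulated data with 50 changed genes per effect size among 14830. The simulated noise was normal and independent between genes and arrays, without weak arrays, correlated genes or a background floor. The shares and false calls below therefore check the fitting steps and may not carry over to the real arrays. For the TE difference in transformed cells, 4% of log2 changes of 0.5, 42% of 1 and 96% of 2 were recovered, with 6 false calls. For the total RNA difference in transformed cells the shares were 54%, 94% and 98%, with 6 false calls, and for the TE difference between states 0%, 4% and 72%, with 2.

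Alternatives were no filter, quantile normalization repeated within each fraction, arrays centred on the median, eBayes with trend and robust settings, array weights, other block choices, only the cultures of a state, the total value as a covariate, probe sets tested separately, and leaving out each embryo. The 2 polysomal arrays that correlated least with the others, untransformed WT embryo 1 (0.874) and transformed WT embryo 3 (0.907), were also left out. In the TE fits with embryo as a block, this left the WT change resting on WT embryo 2 alone. TE was also tested among genes above the 75th percentile in polysomal RNA. Both alternatives were chosen after the data were seen. The same holds for repeating the list tests after quantile normalization, after median centring, without the weak arrays and without each embryo, and for the random lists matched on size and mean total RNA. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.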

Results

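Expression was measured in 12 cultures of mouse embryonic fibroblasts, each profiled as total RNA and as RNA from heavy polysomes, where mRNAs carry many ribosomes. The cultures came from 3 WT and 3 Eif4e heterozygous embryos, each untransformed and transformed with Ras and Myc. Total RNA arrays had a median correlation with the other total arrays of 0.960 to 0.976, and polysomal arrays of 0.874 to 0.942. The SD of values over probe sets was 1.71 to 1.81 in total RNA and 1.15 to 1.44 in polysomal RNA. Xist and Y-linked genes showed a male pattern in 1 WT and 1 heterozygous embryo, the same in both states. In polysomal RNA, Y-linked genes in female cells and Xist in male cells had log2 values of 1.96 to 3.30, a measure of background over 28 values.

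Eif4e, which encodes the cap-binding subunit of the eIF4F initiation complex and lies on chromosome 3, was the targeted gene. Its main probe set (10496485) in total RNA of untransformed cells was 9.10 ± 0.10 on the log2 scale in WT and 8.80 ± 0.10 in heterozygous cultures (SD, n = 3), 81.3% of the WT level. In transformed cells it was 9.63 ± 0.20 in WT and 9.05 ± 0.19 in heterozygous cultures (SD, n = 3), 67.2% of the WT level. In both states each heterozygous culture lay below each WT culture, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. In limma the difference was -0.30 (adjusted p = 1) in untransformed and -0.57 (adjusted p = 0.2) in transformed cells. In polysomal RNA the differences were -0.22 (exact permutation p = 0.2) and -0.53 (exact permutation p = 0.4). The untransformed polysomal difference was -0.12 without Het embryo 1, and the transformed was -0.31 without WT embryo 2 and -0.22 without Het embryo 2. A second probe set (10496490) gave -0.11 (exact permutation p = 0.5) and -0.17 (exact permutation p = 0.2) in total RNA, and -0.35 (exact permutation p = 0.1) and -0.19 (exact permutation p = 0.3) in polysomal RNA.

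**Figure D1:**
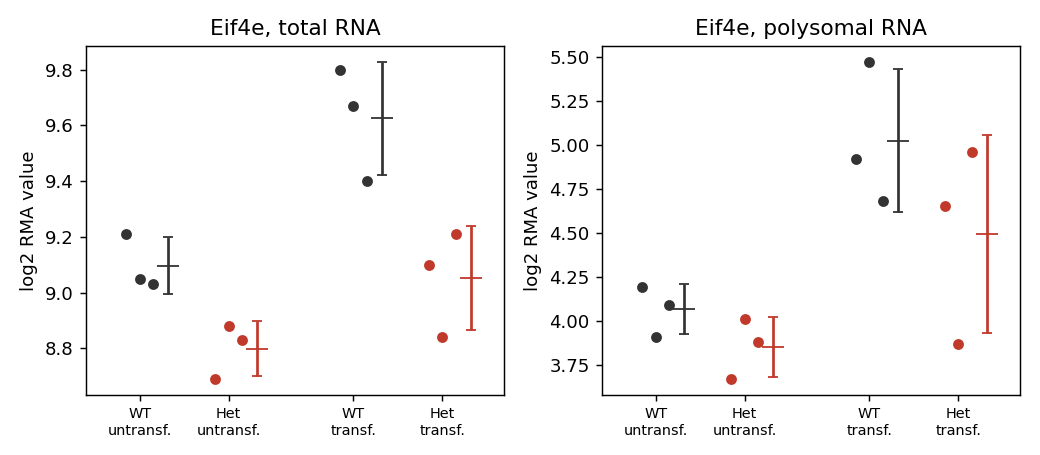
Eif4e log2 RMA value (y axis) per array in total RNA (left) and polysomal RNA (right), with WT in dark grey and heterozygous cultures in red; bars are mean ± SD of 3 cultures, and the axes do not start at 0. In total RNA the heterozygous points lie below the WT points in each state.

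The central question was whether a lower dose of Eif4e changes which mRNAs are translated. Among transformed cells, the mRNAs with the smallest p for higher TE in heterozygous cultures included Uqcr11, a subunit of respiratory complex III (1.07 ± 0.23, SE), the growth factor Fgf7 (1.14 ± 0.28), Mbd3 (0.74 ± 0.18), C3ar1 (1.52 ± 0.36) and Crhbp (0.76 ± 0.19). Those with the smallest p for lower TE included Has2, which makes hyaluronan (-1.43 ± 0.31), Fndc1 (-1.25 ± 0.32), Fam110c (-1.13 ± 0.24), Asxl3 (-0.97 ± 0.21) and the calcium channel gene Cacna1c (-0.78 ± 0.20). None of these passed the test (adjusted p = 1 for each, limma). The total RNA values of the genes with lower TE were higher by 0.80 to 1.46, while their polysomal values differed by -0.01 to 0.10. With limma 0 genes were called, 430 of 14830 had an unadjusted p under 0.05, and limma with array weights or with trend and robust settings also called 0.

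Gene groups tied to eIF4E showed small TE differences in transformed cells. The median Het minus WT difference was -0.06 over 28 mRNAs reported as eIF4E-sensitive (adjusted p = 0.824), 0.08 over 22 ribosomal proteins (adjusted p = 0.288) and 0.02 over 55 redox genes (adjusted p = 0.366), with 0 members called, also when adjusted over the list alone. Eif4e itself differed by 0.04, the translational repressor Eif4ebp1 by 0.24, the helicase Eif4a2 by -0.48 and Paip1, a poly(A)-binding protein partner, by 0.97, none of which passed. Mitochondrial ribosomal proteins were higher as a list (71 genes, median 0.11, camera adjusted p = 0.0402, but adjusted p = 0.954 with an estimated correlation), with Mrps11 at 0.64 and Mrpl2 at 0.52. That call was lost without WT embryo 3 (adjusted p = 0.152), Het embryo 1 (0.0525) or Het embryo 3 (0.986, direction lower), after quantile normalization (0.0903) and without the 2 weak polysomal arrays (0.131).

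In untransformed cells 9 lists had higher TE in heterozygous cultures at the preset correlation. Cholesterol synthesis genes, among them Sqle (0.57) and Scd2 (0.63), had a median of 0.25 (23 of 25 positive, camera adjusted p = 3.36e-05), and other TOP mRNAs, among them Eef2 (0.36) and Eef1a1 (0.47), a median of 0.30 (adjusted p = 0.00271). The extracellular matrix (0.16, led by Pcolce at 0.68 and Col8a1 at 0.40) and replication-dependent histones (0.17, led by H2bc9 at 0.79) had an adjusted p of 0.00271 each. Also higher were contractile genes (0.21, 0.0118), ATF4 stress response (0.17, 0.0177), RAS-ERK output (0.18, 0.0187, led by Hbegf at 0.71), other initiation factors (0.21, 0.0215, led by Eif3h at 0.61) and MYC ribosome biogenesis (0.19, 0.0315, led by Nop56 at 0.68). With an estimated correlation these 9 lists had adjusted p = 0.703 to 0.947, and after quantile normalization within each fraction only cholesterol synthesis was called (adjusted p = 0.00103), while the other 8 kept their direction (0.09 to 0.18). The exact permutation p of the list means was 0.2 for cholesterol synthesis, 0.3 for contractile genes, RAS-ERK output and histones, 0.4 for other TOP mRNAs, 0.5 for ATF4 and 0.6 for the matrix, initiation factors and MYC ribosome biogenesis. For other TOP mRNAs, initiation factors, MYC ribosome biogenesis and ATF4 the mean of WT embryo 3 (-3.54, -3.54, -3.84 and -3.87) lay above each heterozygous culture. Without the 2 weak polysomal arrays the calls of other TOP mRNAs (0.0842), initiation factors (0.829), MYC ribosome biogenesis (0.752) and ATF4 (0.257) were lost.

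Single mRNAs did not pass in untransformed cells. The smallest p-values for higher TE belonged to Laptm4b (0.67 ± 0.17, SE), Gprc5b (0.73 ± 0.18), Pigk (0.84 ± 0.21), Rarres1 (0.79 ± 0.20) and H2bc9 (0.79 ± 0.20), and for lower TE to Fancm (-0.73 ± 0.20), Fetub (-0.57 ± 0.18), G6pd2 (-0.62 ± 0.20), Oip5 (-0.55 ± 0.18) and Phtf1os (-1.07 ± 0.36). With limma 0 genes were called and 215 had an unadjusted p under 0.05; array weights and trend with robust settings also called 0. The eIF4E-sensitive list had a median of 0.10 (adjusted p = 0.594) and 1 histone gene passed when adjusted over the list alone. Of the 9 lists, cholesterol synthesis was called without each embryo in turn. Contractile genes lost the call without WT embryo 2 (adjusted p = 0.539) or Het embryo 2 (0.0588), other TOP mRNAs without WT embryo 1 (0.0738) or WT embryo 2 (0.299), and extracellular matrix without WT embryo 3 (0.0947, direction lower) or Het embryo 3 (0.722). Histones lost it without WT embryo 2 (0.0678), WT embryo 3 (0.528) or Het embryo 1 (0.413), and RAS-ERK output without WT embryo 1 (0.0533), WT embryo 2 (0.14), WT embryo 3 (0.0673) or Het embryo 1 (0.218). Another 3 lists lost the call in 4 removals each. Without WT embryo 1, WT embryo 2, Het embryo 1 or Het embryo 2 the adjusted p was 0.829, 0.539, 0.0906 and 0.128 for other initiation factors, 0.792, 0.997 (direction lower), 0.0809 and 0.243 for MYC ribosome biogenesis, and 0.283, 0.176, 0.263 and 0.0533 for the ATF4 stress response.

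In total RNA of transformed cells 7 genes differed between the genotypes. Cadm1, a cell adhesion molecule (-1.62 ± 0.19, SE, adjusted p = 0.0236), Pxdc1 (-1.29 ± 0.17, 0.0397), Enthd1 (-1.22 ± 0.15, 0.0316), Fer1l6 (-0.80 ± 0.11, 0.0397), the lipid kinase gene Pip5k1b (-0.78 ± 0.08, 0.0157) and the ubiquitin ligase gene Rnf213 (-0.72 ± 0.10, 0.0498) were lower in heterozygous cultures. Ahi1 was higher (0.75 ± 0.10, adjusted p = 0.0404). Next in order of p, not passing, came S100g (0.76, adjusted p = 0.0702), Zdhhc15 (0.67, 0.0775), the imprinted gene Dlk1 (0.97, 0.0896) and Asxl3 (1.08, 0.1). In limma 1379 genes had an unadjusted p under 0.05. The count of 7 moved to 14 without WT embryo 1, 51 without WT embryo 2, 1 without WT embryo 3, 0 without Het embryo 1, 3 without Het embryo 2 and 2 without Het embryo 3. Of the 7 genes 5 were called without WT embryo 1, 6 without WT embryo 2 and 0 without WT embryo 3, Het embryo 1, Het embryo 2 or Het embryo 3. With limma on the transformed cultures alone 0 genes were called, with 707 at an unadjusted p under 0.05.

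Contractile and matrix genes of myofibroblasts were among the lists that were higher in that comparison. Contractile genes had a median of 0.22 (16 of 24 positive, camera adjusted p = 0.00623), with the smooth muscle genes Tagln (1.92), Myl9 (1.71), Acta2 (1.66) and Cnn1 (1.39), and extracellular matrix genes 0.21 (40 of 56 positive, 7.91e-05), with Fbn2 (1.67), Fbln2 (1.25) and the collagens Col6a1 (0.83) and Col6a2 (0.62). Adjusted over the list alone, 4 contractile genes were higher, and 7 matrix genes were higher and 1 lower, against 0 over all genes; 1 redox gene was lower over the list alone. MYC ribosome biogenesis (0.17, 44 of 46 positive, 2.91e-06), S phase (0.12, 0.015), G2 and mitosis (0.12, 0.0202), cholesterol synthesis (0.18, 0.0347) and neural markers (0.24, 0.0347) were also higher as lists. Redox genes (-0.07, 0.0202, with the sulfiredoxin gene Srxn1 at -0.75 and Gpx1 at -0.34), oxidative phosphorylation (-0.04, 0.0202, with Uqcr10 at -0.34) and endothelial markers (-0.08, 0.045, with Eng at -0.61) were lower. For all 10 lists adjusted p = 0.869 with an estimated correlation. The exact permutation p of the list means was 0.1 for endothelial markers, 0.2 for contractile genes and 0.3 for G2 and mitosis and neural markers. It was 0.4 for MYC ribosome biogenesis, 0.5 for matrix, S phase, redox and cholesterol synthesis and 0.7 for oxidative phosphorylation. The contractile mean of Het embryo 3 (9.80) lay below that of WT embryo 3 (10.33). The matrix call was lost without WT embryo 1 (adjusted p = 0.0849) or Het embryo 2 (0.313), the contractile call without WT embryo 1 (0.388), WT embryo 2 (0.0627) or Het embryo 2 (0.833), and the MYC call without WT embryo 3 (0.175). S phase lost it without WT embryo 3 (0.783) or Het embryo 1 (0.688), and G2 and mitosis without WT embryo 3 (0.48), Het embryo 1 (0.265) or Het embryo 3 (0.364). Redox genes lost it without WT embryo 2 (0.0627), WT embryo 3 (0.631), Het embryo 1 (0.116) or Het embryo 3 (0.476), and oxidative phosphorylation without WT embryo 2 (0.0738), WT embryo 3 (0.0568) or Het embryo 3 (0.889). Cholesterol synthesis lost it without WT embryo 1 (0.964), Het embryo 1 (0.116) or Het embryo 2 (0.62), neural markers without WT embryo 1 (0.132), WT embryo 3 (0.0568) or Het embryo 2 (0.221), and endothelial markers without WT embryo 1 (0.105), WT embryo 2 (0.0627), WT embryo 3 (0.0568), Het embryo 1 (0.116) or Het embryo 2 (0.221). Oxidative phosphorylation also lost it after quantile normalization (0.0607) and endothelial markers after centring (0.053).

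In total RNA of untransformed cells, genes of cell division were higher as lists in heterozygous cultures at the preset correlation, but not in each culture. All 40 measured G2 and mitosis genes had positive differences (median 0.34, camera adjusted p = 2.39e-35), with Ccnb2, a mitotic cyclin (0.35), the phosphatase gene Cdc25c (0.51), the proliferation marker Mki67 (0.44) and Prc1 (0.34). All 41 S phase genes were also positive (median 0.24, 9.13e-21), with Tk1 (0.31), Lig1 (0.34), the polymerase gene Pole (0.54) and the helicase gene Mcm6 (0.30), and MYC ribosome biogenesis had a median of 0.11 (44 of 46 positive, 3.46e-08). p53 targets were lower (median -0.10, 21 of 25 negative, 0.000317), with Tnfrsf10b (-0.27), Trp53inp1 (-0.37), Mdm2 (-0.23) and Perp (-0.77). These 4 lists had, with an estimated correlation, adjusted p = 0.358 (G2 and mitosis), 0.401 (S phase), 0.663 (MYC ribosome biogenesis) and 0.358 (p53 targets). Averaged per culture, the G2 and mitosis list was 9.83 ± 0.25 in WT and 10.16 ± 0.18 in heterozygous cultures (SD, n = 3, exact two-sided permutation p = 0.2), the S phase list 9.17 ± 0.24 and 9.42 ± 0.08 (exact permutation p = 0.3), and the p53 list 9.23 ± 0.09 and 9.10 ± 0.03 (exact permutation p = 0.1). The differences in list means were 0.33, 0.25 and -0.13. WT embryo 1 lay above Het embryo 2 in the G2 and mitosis mean (10.115 against 9.97). It also lay above Het embryos 2 and 3 in the S phase mean (9.43 against 9.37 each). These 4 list calls held without each embryo in turn.

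Smaller list differences and single genes made up the rest of that comparison. Other initiation factors (median 0.05, camera adjusted p = 0.00176), ATF4 stress response (0.11, 0.0084), other TOP mRNAs (0.04, 0.0282) and ribosomal proteins (0.06, 0.0429) were higher, and endothelial markers lower (-0.06, 0.019), in each case at the preset correlation. The same lists had adjusted p = 0.657, 0.938, 0.61, 0.882 and 0.358 with an estimated correlation. These calls were lost without WT embryo 2 for initiation factors (0.162), without WT embryo 1 (0.467) or Het embryo 3 (0.241, direction lower) for ATF4, and without WT embryo 1 (0.153) or Het embryo 2 (0.0785) for endothelial markers. Other TOP mRNAs lost it without WT embryo 1 (0.137), WT embryo 2 (0.138), Het embryo 1 (0.0797) or Het embryo 2 (0.0785), and ribosomal proteins without WT embryo 1 (0.151), WT embryo 2 (0.242) or Het embryo 3 (0.241), and after quantile normalization (0.137). The endothelial sialomucin gene Emcn had the smallest p of all genes (-0.73 ± 0.11, SE, adjusted p = 0.378) and passed when adjusted over the list alone. Other small p-values included Rttn (0.42), Cntln (0.39) and the condensin gene Ncapd2 (0.41) among higher genes, and Gja4 (-0.29) and Mmp12 (-0.49) among lower genes, each with adjusted p = 1. With limma 0 genes were called and 352 had an unadjusted p under 0.05; array weights and trend with robust settings also called 0.

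Polysomal RNA, the other part of TE, showed the same contractile genes in transformed cells. The smallest p for higher values in heterozygous cultures belonged, in order, to Tagln (2.20 ± 0.38, SE, adjusted p = 0.289), S100g (1.36 ± 0.30), Myl9 (1.78 ± 0.41), Cnn1 (2.48 ± 0.58) and Frat2 (0.72 ± 0.17). S100g and Frat2 are not on the contractile list, and the Cnn1 values of the genotypes overlapped. For lower values it belonged to Enthd1 (-1.52 ± 0.21, adjusted p = 0.072), Csta2 (-1.65 ± 0.23, 0.072), the oxygen sensor gene Egln3 (-1.48 ± 0.26, 0.289) and Pxdc1 (-1.14 ± 0.22, 0.663). None of these genes passed the test. The lists called were contractile genes (median 0.16, camera adjusted p = 0.000749), extracellular matrix (0.10, 0.00608), mitochondrial ribosomal proteins (0.13, 0.00608), MYC ribosome biogenesis (0.15, 0.0373) and histones (0.23, 0.0415), each with adjusted p = 0.982 with an estimated correlation. The exact permutation p of these list means ranged from 0.3 (contractile genes) to 0.7 (MYC ribosome biogenesis). Adjusted over the list alone, 4 contractile genes were higher and 1 histone gene lower, against 0 over all genes. Contractile genes lost the call without WT embryo 1 (0.205), Het embryo 1 (0.0609) or Het embryo 2 (0.0811), extracellular matrix without WT embryo 1 (0.317) or Het embryo 2 (0.767), and mitochondrial ribosomal proteins without WT embryo 3 (0.478), Het embryo 1 (0.228) or Het embryo 3 (0.671). MYC ribosome biogenesis lost it without WT embryo 3 (0.317, direction lower), Het embryo 1 (0.884) or Het embryo 3 (0.0645), and histones without WT embryo 1 (0.53), WT embryo 2 (0.131), Het embryo 2 (0.0991) or Het embryo 3 (0.118). Without the 2 weak polysomal arrays the calls of mitochondrial ribosomal proteins (0.516) and MYC ribosome biogenesis (0.621, direction lower) were lost, and after quantile normalization that of histones (0.068). With limma 0 genes were called and 478 had an unadjusted p under 0.05, while trend with robust settings and array weights each called 2.

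In untransformed cells cell division genes were higher as lists in polysomal RNA of heterozygous cultures at the preset correlation, but not in each culture. G2 and mitosis genes had a median of 0.32 (40 of 40 positive, camera adjusted p = 1.45e-09), with Plk1 (0.65), Ube2c (0.52) and Bub1b (0.78), and S phase genes 0.26 (39 of 41 positive, 2.28e-08), with Mcm2 (0.69), Uhrf1 (0.74) and Rrm2 (0.91). MYC ribosome biogenesis (0.31, 2.42e-05), ATF4 stress response (0.29, 2.42e-05), other TOP mRNAs (0.35, 4.97e-05), cholesterol synthesis (0.27, 4.97e-05), histones (0.33, 0.0001), other initiation factors (0.24, 0.000436) and contractile genes (0.18, 0.0287) were higher and muscle markers lower (-0.14, 0.0421). With an estimated correlation these 10 lists had adjusted p = 0.54 to 0.571. The G2 and mitosis mean of WT embryo 3 (5.13) lay above all heterozygous cultures (4.92 to 5.10), with an exact permutation p of 0.4, and that of S phase was 0.3. After quantile normalization the calls of contractile genes (0.276) and muscle markers (0.0538; 0.0581 after centring) were lost. Without the 2 weak polysomal arrays those of initiation factors (0.211), ATF4 (0.0558) and muscle markers (0.39) were lost. G2 and mitosis kept its call without each embryo. Without WT embryo 2 the adjusted p was 0.0687 for S phase, 0.263 for MYC ribosome biogenesis, 0.0687 for other TOP mRNAs, 0.208 for initiation factors (0.187 without WT embryo 1) and 0.618 for contractile genes (0.198 without Het embryo 2). Histones lost the call without WT embryo 3 (0.413) or Het embryo 1 (0.113), ATF4 without Het embryo 3 (0.0611), cholesterol synthesis without WT embryo 3 (0.104), and muscle markers without WT embryo 1 (0.401), WT embryo 3 (0.0997), Het embryo 1 (0.0965) or Het embryo 2 (0.14). With limma 0 genes were called and 247 had an unadjusted p under 0.05; array weights and trend with robust settings also called 0.

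Whether the genotype effect differed between the states was tested as an interaction, transformed minus untransformed. In total RNA the smallest p-values belonged to Acer2 (1.00), Gzme (1.10) and Ahi1 (0.83) in the positive direction and Cadm1 (-1.52), Ly75 (-0.71) and Pip5k1b (-0.88) in the negative direction, each with adjusted p = 0.81. In TE they belonged to Serf2 (1.28) and Srsf9 (1.47), and to Adgrl2 (-1.18) and Has2 (-1.94), each with adjusted p = 1. For Eif4e the interaction was -0.27 in total RNA (adjusted p = 0.916) and -0.04 in TE (adjusted p = 1). With limma 0 genes were called in either measure, with 723 and 289 at an unadjusted p under 0.05, and array weights or trend with robust settings called 0.

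Transformation of WT cells lowered the contractile and matrix program of fibroblasts. Of 24 contractile genes 22 fell in total RNA, among them the myosin light chain gene Myl9 (-4.88 ± 0.35, SE, adjusted p = 0.000837), the calponin gene Cnn1 (-4.37 ± 0.27, 0.000534), Tagln (-4.21 ± 0.30, 0.000846) and the smooth muscle actin gene Actg2 (-4.30 ± 0.41, 0.0018). Of 56 extracellular matrix genes 36 fell, among them periostin (Postn, -5.15 ± 0.76, 0.00712), Fbln2 (-2.59), Ltbp2 (-2.35) and Lama2 (-2.29). Adjusted over the list alone, 24 contractile and 45 matrix genes fell and 1 matrix gene rose. The list medians were -1.23 and -1.01 (camera adjusted p = 2.46e-18 each, and adjusted p = 0.506 each with an estimated correlation). The protease gene Tll1 fell by 5.57 on the log2 scale (adjusted p = 8.51e-05), Ptprz1 by 4.63, Alkal1 by 4.23 and Cdh10 by 4.13.

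Genes that rose in WT cells included the aldo-keto reductase gene Akr1c18 (3.09 ± 0.41, SE, adjusted p = 0.00488), the neurofilament gene Nefl (3.04 ± 0.51, 0.0108), Fndc3c1 (2.92 ± 0.31, 0.00256), Mgst2 (2.85), the phosphatase gene Inpp4b (2.75), Bmp2 (2.75), Hao1 (2.71), the chloride channel gene Ano1 (2.66), Tmprss11f (3.14) and D5Ertd615e (2.96). Eif4e rose by 0.53 (adjusted p = 0.0204), as did Pabpc1 (0.36, 0.0175), Paip2 (0.36, 0.0142) and the eIF4A inhibitor Pdcd4 (0.91, 0.00748). These 4 of 17 eIF4F members rose and 0 fell, against 5 and 0 when adjusted over the list alone (median 0.11, camera adjusted p = 0.0528). Mitochondrial ribosomal proteins rose in 14 of 71 cases (17 adjusted over the list alone; median 0.23, camera adjusted p = 2.31e-08), with Mrpl13 (0.81) and Mrps35 (0.64), and MYC ribosome biogenesis genes in 7 of 46 (5 over the list alone; 0.23, 2.04e-05), with Ddx18 (0.47) and Polr1e (0.59). Oxidative phosphorylation genes rose in 6 of 64 cases (0 over the list alone; 0.13, 0.00126), with Uqcr11 (0.57). Adjusted p = 0.603 with an estimated correlation for each of these 3 lists.

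Of 25 genes on the p53 target list 8 rose and 3 fell in WT cells (11 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.00742, and adjusted p = 0.506 with an estimated correlation), with Mdm2 (0.87) and Trp53inp1 (0.89) among the rises. Cdkn2a (0.68), which the fixed list also held, acts upstream of p53 and is not a p53 target. Of 28 mRNAs reported as eIF4E-sensitive 9 fell and 3 rose (10 and 3 over the list alone; -0.14, 0.049, and adjusted p = 0.603 with an estimated correlation), with Vegfc (-1.45), Snai1 (-0.46) and Myc (-1.91) among the falls. Whether the Myc probe set reads the introduced Myc was not tested. Markers of cell types also fell. They were 7 of 11 leukocyte genes, with lysozyme (Lyz2, -4.14) and Tyrobp (-1.42), median -0.61 (0.00374). Another 4 of 10 neural genes fell, with Stmn2 (-3.33) and Tubb3 (-2.64), median -0.19 (0.0374), and 6 of 15 fibroblast genes, with Thy1 (-3.53), Pdgfrb (-2.61) and Col1a2 (-2.16), median -0.30 (0.0172). Adjusted over the list alone, 7, 5 and 6 fell, and 2, 2 and 1 rose, against 1, 1 and 0 rises over all genes. These 3 lists had adjusted p = 0.506, 0.603 and 0.603 with an estimated correlation. The p53 call was lost without WT embryo 3 (0.0614), the neural call without WT embryo 2 (0.0759) or WT embryo 3 (0.0813), the fibroblast call without WT embryo 1 (0.184), and the eIF4E-sensitive call without WT embryo 1 (0.162), WT embryo 3 (0.111), Het embryo 1 (0.0563), Het embryo 2 (0.0536) or Het embryo 3 (0.0518), and after quantile normalization (0.051).

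Further lists in WT cells were other initiation factors (1 of 24 rose, Eif3h at 0.40; median 0.15), ribosomal proteins (1 of 22 rose, Rpl23 at 0.46; 0.16) and other TOP mRNAs (2 of 14 rose, 3 over the list alone; 0.11), each with camera adjusted p = 0.0159. G2 and mitosis genes rose in 5 of 40 cases (0 over the list alone; 0.14, 0.0198), with Cenpa (0.62) and Bub1b (0.46), and ATF4 genes fell in 3 of 36 (0 over the list alone; -0.18, 0.0198), with the arginine transporter gene Slc7a1 (-0.36). With an estimated correlation adjusted p = 0.603, 0.603, 0.506, 0.747 and 0.747. Each of these 5 calls was lost without WT embryo 2 (0.201, 0.11, 0.0759, 0.999 with the direction lower, and 0.11). In all, 1130 genes rose and 1346 fell (limma, 4782 with an unadjusted p under 0.05), and the total of 2476 was 952 without WT embryo 1 and 1158 without WT embryo 2.

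In heterozygous cells 10 lists were called on transformation, against 15 in WT cells. That contrast depended on the scaling: after quantile normalization 15 lists were called in each genotype, and after median centring 12 in heterozygous and 15 in WT cells. Of 24 contractile genes 23 fell (24 over the list alone; median -1.14, camera adjusted p = 3.2e-18), with Cnn1 (-2.88), Ccn2 (-2.32) and the integrin gene Itga5 (-1.31), and of 56 matrix genes 26 fell and 1 rose (39 and 1 over the list alone; -0.74, 4.04e-14), with Timp3 (-2.93), Lama2 (-2.16) and Fmod (-1.86). Tll1 (-4.87), Ptprz1 (-4.46), Tnmd (-3.93), Lyz2 (-3.81), Cdh10 (-3.61), Zdbf2 (-3.58) and Tfpi2 (-3.55) were among the largest falls, and the ion channel gene Trpa1 (3.76), Cd34 (3.05), Fndc3c1 (3.03), the stem cell factor Sox2 (3.02), Akr1c18 (2.99), Slitrk6 (2.95) and Esm1 (2.87) among the largest rises. Eif4e was higher by 0.25, which did not pass (adjusted p = 0.165), while Pdcd4 (0.91) and Paip2 (0.39) rose and Eif4e3 fell (-0.64, adjusted p = 0.0451). Genes on the p53 target list rose in 7 of 25 cases (12 over the list alone, where 2 fell; 0.26, 9.5e-05), with Perp (2.70) and Trp53inp1 (1.35). Cdkn2a (0.99), on the list but upstream of p53, was also higher. Adjusted p = 0.564 with an estimated correlation for contractile genes and p53 targets and 0.668 for the matrix.

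Mitochondrial ribosomal proteins rose in 14 of 71 cases in heterozygous cells (21 over the list alone; median 0.22, camera adjusted p = 4.24e-07), with Mrpl38 (0.52), and MYC ribosome biogenesis genes in 6 of 46 (14 over the list alone; 0.28, 1.02e-06), with Polr1e (0.69) and Cad (0.61). Leukocyte markers fell in 7 of 11 cases (7 over the list alone, where 1 rose; -0.53, 0.000407). These 3 lists had adjusted p = 0.723, 0.723 and 0.564 with an estimated correlation. ATF4 genes (1 rose and 2 fell of 36; 1 and 1 over the list alone; -0.29, 0.00116), eIF4E-sensitive mRNAs (2 rose and 6 fell of 28; 2 and 8 over the list alone; -0.15, 0.0251), ribosomal proteins (1 of 22 rose, 0 over the list alone; 0.11, 0.0412) and fibroblast markers (4 of 15 fell, 5 over the list alone; -0.09, 0.0436) completed the called lists, with adjusted p = 0.723 with an estimated correlation. Called in WT cells only, on the values as deposited, were other initiation factors (here 0.13, 0.061), other TOP mRNAs (0.10, 0.151), oxidative phosphorylation (0.07, 0.0711), G2 and mitosis (-0.07, 0.104) and neural markers (-0.15, 0.0916). This compares calls and not effects. Of these lists only G2 and mitosis was called in the interaction test in total RNA. Calls were lost without Het embryo 3 for ATF4 (0.74), Het embryo 1 (0.0577) or Het embryo 2 (0.0521) for eIF4E-sensitive mRNAs, Het embryo 1 (0.206) or Het embryo 2 (0.205) for ribosomal proteins, and WT embryo 1 (0.0651), WT embryo 3 (0.0808) or Het embryo 1 (0.197) for fibroblast markers. In all, 842 genes rose and 1273 fell (limma, 4650 with an unadjusted p under 0.05). The total of 2115 was 562 without Het embryo 1, 1325 without Het embryo 2 and 326 without Het embryo 3.

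**Figure D2:**
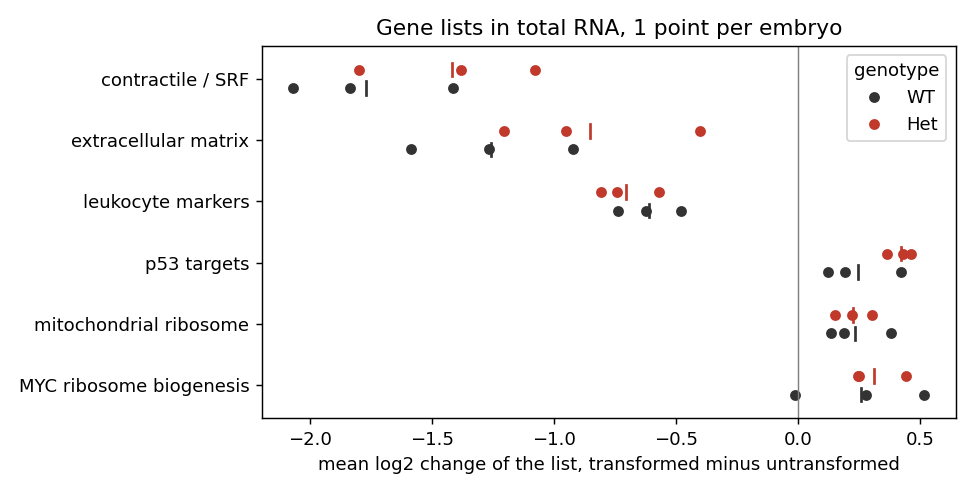
Mean log2 change of 6 gene lists in total RNA (x axis, transformed minus untransformed), with 1 point per embryo and a vertical tick at the mean of 3 embryos; WT in dark grey, heterozygous in red. Contractile genes fell by 1.77 ± 0.33 (SD) in WT and by 1.42 ± 0.36 in heterozygous embryos on average.

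The genotypes shared most transformation calls in total RNA. Of the rising genes 600 were shared, where independent lists of those sizes would share 64.2, and of the falling genes 949 were shared against 115.5, with 0 genes called in opposite directions. Across 14830 genes, which are not independent replicates, the changes correlated at r = 0.873 (rho = 0.759) in total RNA, 0.758 (0.584) in polysomal RNA and 0.646 (0.526) in TE. No embryo was shared between the genotypes, although both effects used a common estimate of the spread.

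On transformation some mRNAs passed the test for TE, in numbers that depended on the embryos and settings used. In both genotypes the prostaglandin synthase gene Ptgs2 (WT -2.13 ± 0.27, SE, adjusted p = 0.0185; Het -2.74 ± 0.27, 0.00643), the matrix gene Thbs1 (WT -2.42 ± 0.29, 0.014; Het -2.45 ± 0.29, 0.0144) and the actin gene Acta2 (WT -1.66 ± 0.19, 0.0129; Het -1.79 ± 0.19, 0.00836) fell in TE. In total RNA Thbs1 (-2.23 in WT and -1.32 in heterozygous cells) and Acta2 (-3.46 and -1.79) fell too, while Ptgs2 (-1.48, adjusted p = 0.0645, and -1.21, adjusted p = 0.117) did not pass. TE rose in WT cells for the ferritin gene Fth1 (1.70 ± 0.20, 0.014) and the polyamine enzyme gene Odc1 (1.56 ± 0.24, 0.0292), and in heterozygous cells for Lsm5 (2.98 ± 0.36, 0.0144), while the chaperone gene Hspa5 fell (-1.63 ± 0.25, 0.0448). The largest rises in WT cells were Ptprz1 (3.99), Rian (3.10), Epha3 (3.03), Tnmd (2.96), Alkal1 (2.93), Cdh10 (2.88), Tfpi2 (2.79), Lrrc4c (2.69), Lyz2 (2.62) and Il6 (2.61), all of which fell in total RNA. With the total value as a covariate Ptprz1 (-1.32), Epha3 (-0.87), Lyz2 (-0.13) and Il6 (-0.16) turned direction. These covariate estimates extend a slope fitted per gene over the change in total RNA, so their direction may be imprecise. Of the 104 genes called in WT cells 47 lay at polysomal background in both states. Falls in TE of Klra2 (-2.31), Il33 (-2.31), Tmprss11f (-2.29), Ifi209 (-2.25), D5Ertd615e (-2.24), Mgat4a (-2.13), Inpp4b (-2.02) and Akr1c18 (-1.83) came with higher total RNA. In heterozygous cells Ptprz1 (3.41), Tnmd (2.97), Clca3a1 (2.92), Zdbf2 (2.91), Tfpi2 (2.65), Olr1 (2.34) and Ptprd (2.31) rose and Ifi209 (-2.47), Mgat4a (-2.15), Osbpl6 (-1.89), Fndc3c1 (-1.84) and Tex15 (-1.82) fell.

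The TE calls numbered 75 up and 29 down in WT cells and 30 up and 14 down in heterozygous cells (limma, 1487 and 1524 with an unadjusted p under 0.05), and 25 rises and 7 falls were shared against 0.2 and 0 for independent lists. In WT cells 97 of the 104 called genes changed in TE against the direction of total RNA (93.3%), with a median absolute change of 2.15 in total and 0.41 in polysomal RNA. In heterozygous cells this held for 38 of 44 (86.4%), with 2.01 and 0.38. With the total value as a covariate 0 genes were called in either genotype. That fit carries the error of each gene's slope into the estimate, and this error grows with the change in total RNA. Of the called genes 98 of 104 in WT and 39 of 44 in heterozygous cells were also called in total RNA. Losing their calls in the covariate fit therefore says little about TE. Among genes bright in polysomal RNA 0 were called in WT and 4 in heterozygous cells. The WT count was 24 without WT embryo 1, 14 without WT embryo 2, 881 without WT embryo 3, 25 without Het embryo 1, 23 without Het embryo 2 and 27 without Het embryo 3. The heterozygous count was 540 without WT embryo 3 and 0 without Het embryo 1, Het embryo 2 or Het embryo 3.

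**Figure D3:**
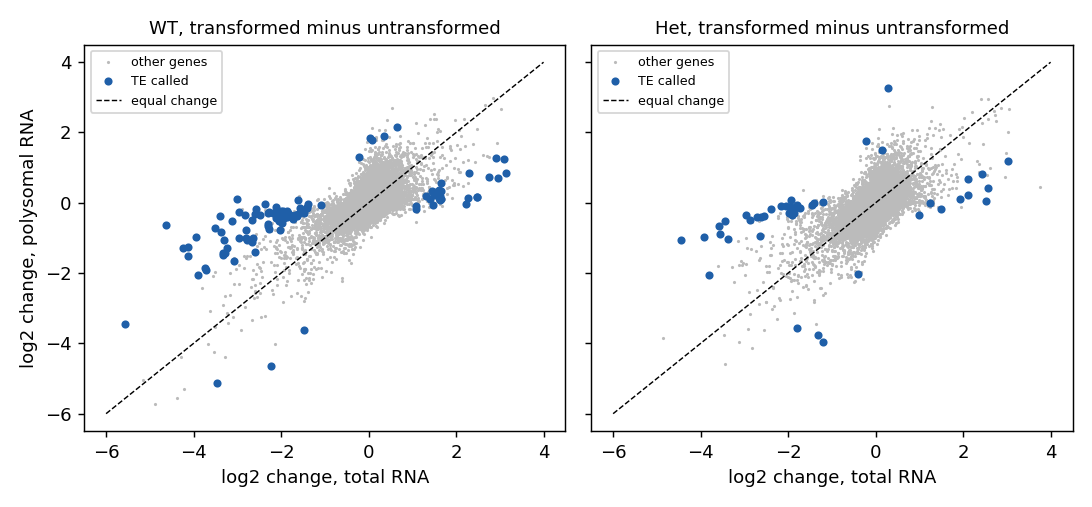
Log2 change on transformation in polysomal RNA (y axis) against total RNA (x axis) for 14830 genes in WT (left) and heterozygous cells (right); blue points are genes called in TE and the dashed line marks equal change. Most of the 104 and 44 blue points changed in total RNA with a smaller change in polysomal RNA.

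Several lists had higher TE on transformation at the preset correlation, with oxidative phosphorylation, histone, ribosomal, mitochondrial ribosomal and redox genes called in both genotypes. Oxidative phosphorylation genes had a median of 0.48 in WT (60 of 64 positive, camera adjusted p = 1.97e-09) and 0.44 in heterozygous cells (2.79e-11), with Cox7b at 1.06 and 1.21. Replication-dependent histones had 0.69 (1 of 22 rose, 10 over the list alone; 1.97e-09) and 0.55 (0 rose, 6 over the list alone; 2e-08), mitochondrial ribosomal proteins 0.30 (3.42e-05) and 0.37 (0 rose, 1 over the list alone; 1.25e-09), ribosomal proteins 0.34 (0.00431) and 0.35 (0.000182), and redox genes 0.12 (1 rose, 3 over the list alone; 0.0191) and 0.20 (0.00504). Other lists of the translation machinery were not called in WT or heterozygous cells: eIF4F and its regulators had medians of 0.28 and 0.06 (0.148 and 0.429), other initiation factors 0.30 and 0.08 (0.0671 and 0.788), and other TOP mRNAs 0.32 and -0.10 (0.148 and 0.634). Contractile genes were lower at -0.38 (1 fell, 8 over the list alone, where 1 rose; 2.07e-07) and -0.47 (1 fell, 8 over the list alone; 9.31e-09). MYC ribosome biogenesis was higher in WT cells (1 rose, 2 over the list alone; 0.32, 0.0248). In heterozygous cells the matrix (2 rose and 1 fell, 2 and 6 over the list alone; -0.29, 4.5e-05) and cholesterol synthesis (-0.21, 0.0168) were lower and endothelial markers higher (1 rose, 3 over the list alone; 0.13, 0.017, with Emcn at 1.96). The endothelial list mean changed by -0.61 in total RNA of these cells. Its polysomal means of 3.16 to 3.41 lay near the highest background value of 3.30. With an estimated correlation adjusted p = 0.764 for the 7 lists in WT cells and 0.666 to 0.919 for the 9 in heterozygous cells. Without WT embryo 1 the WT calls were lost for mitochondrial ribosomal proteins (0.17), ribosomal proteins (0.111), redox genes (0.644) and MYC ribosome biogenesis (0.547; 0.652 without WT embryo 2). In heterozygous cells redox genes lost it without Het embryo 3 (0.235), cholesterol synthesis without Het embryo 2 (0.396) and endothelial markers without Het embryo 1 (0.0868). Without the 2 weak polysomal arrays the WT effect came from WT embryo 2 alone, so no list calls are given for that setting. In that embryo oxidative phosphorylation changed by 0.11 as a list mean (0.44 over 3 WT embryos) and mitochondrial ribosomal proteins by 0.21 (0.32). Ribosomal proteins changed by 0.135 (0.32), redox genes by 0.19 (0.26) and contractile genes by -0.14 (-0.50). MYC ribosome biogenesis changed by 0.63 (0.26) and histones by 0.60 (0.68). After quantile normalization the WT calls of ribosomal proteins, redox genes and MYC ribosome biogenesis were lost (0.133 each).

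Which mRNAs sat on heavy polysomes could be read only relative to the median gene, because the fractions had separate levels. In WT cells replication-dependent histones had a median relative TE of 2.49 untransformed and 3.60 transformed, above all 10000 random lists matched on size and mean total RNA. Oxidative phosphorylation (0.54 and 0.92) also lay at the 100th percentile in both states, and G2 and mitosis (-1.14 and -1.15) at percentiles 0.61 and 0.29. Nuclear noncoding RNAs, expected to be low on polysomes, had medians of -0.75 and -0.56, at percentiles 10.23 and 16.61, which did not set the list apart. Contractile genes had 0.67 and 0.34 (percentiles 100 and 98.95) and interferon response 0.25 and 0.20 (0.16 and 0.08). Among single noncoding RNAs kept largely in the nucleus, Malat1 had a relative TE of -4.23 ± 0.64 and -3.45 ± 0.91 and Meg3 -3.32 ± 0.42 and -1.01 ± 1.34, while Actb, a well translated mRNA, had 2.49 ± 0.25 and 2.39 ± 0.18 (SD, n = 3, untransformed and transformed). As deposited, the median TE was -3.86 untransformed and -3.80 transformed, and 14825 and 14820 genes differed from 0 (0 and 2 of them higher). After centring each array on its median 10190 and 10231 differed, 6514 and 6669 of them higher.

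Lists that were called in no comparison showed small medians on transformation of WT cells in total RNA. These were eIF4F and its regulators (0.11, camera adjusted p = 0.0528), interferon response (-0.05, 0.604), epithelial markers (-0.05, 0.678), cartilage markers (-0.11, 0.16), adipocyte markers (-0.19, 0.398), nuclear noncoding RNAs (0.10, 0.184) and sex-linked genes (0.10, 0.481). Median and mean differed in sign for epithelial markers (mean 0.18), nuclear noncoding RNAs (mean -0.14) and adipocyte markers (mean 0.09). RAS-ERK output, called in TE of untransformed cells, was not called here and had a median of 0.12 (0.448), with 8 genes up and 5 down in WT cells and 7 up and 4 down in heterozygous cells (10 and 9, and 10 and 5, adjusted over the list alone). Muscle markers, called in polysomal RNA of untransformed cells, had -0.03 (0.247), with 3 of 13 falling.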

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

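The 8 list results below came from the planned test of whether the genotype effect differed between untransformed and transformed cells, while all tests of explanations were chosen after the results were seen. In total RNA the G2 and mitosis list had an interaction median of -0.20 (camera adjusted p = 1.95e-09), S phase -0.14 (0.000354), extracellular matrix 0.29 (7.39e-06), contractile genes 0.16 (0.0195) and p53 targets 0.15 (0.0276), each with adjusted p = 0.929 with an estimated correlation. In TE other TOP mRNAs had -0.36 (0.0487), extracellular matrix -0.31 (3.49e-05) and cholesterol synthesis -0.34 (0.000305), each with adjusted p = 0.921 with an estimated correlation. Without the 2 weak polysomal arrays the WT side of the TE interaction came from WT embryo 2 alone, so list calls under that setting are not given. Without WT embryo 2 the adjusted p was 0.0779 for G2 and mitosis, 0.519 for S phase (0.143 without Het embryo 2), 0.162 for p53 targets (0.16 without WT embryo 1, 0.118 without Het embryo 2) and 0.0864 for contractile genes (0.386 without WT embryo 1, 0.58 without Het embryo 2). The matrix interaction had 0.126 in total RNA without Het embryo 2, and in TE 0.588 without WT embryo 3 and 0.108 without Het embryo 3. In WT embryo 2 the matrix list mean changed in TE by -0.255, against a mean of -0.298 in heterozygous embryos. Other TOP mRNAs had 0.359 without WT embryo 1, 0.518 without WT embryo 2, 0.165 without Het embryo 2, 0.0642 without Het embryo 3 and 0.0541 after quantile normalization, and the cholesterol call held without each embryo.

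Cell division genes were higher as lists in total RNA of untransformed heterozygous cultures at the preset correlation. The difference was positive in 40 of 40 G2 and mitosis genes, but 0 genes were called singly. With an estimated correlation the G2 and mitosis list had a camera adjusted p of 0.358. Rescaling the deposited values did not remove the difference: after quantile normalization within each fraction the G2 and mitosis median was 0.31 (adjusted p = 1e-30) and the S phase median 0.23 (9.81e-18), and after centring 0.34 and 0.23. The deposited values were already RMA values with nearly equal array means in total RNA, so rescaling could change little. It cannot test the authors' own normalization, which stays open as a cause. A chance difference in growth between cultures stays open, since the exact permutation p of the G2 and mitosis list mean was 0.2 and 3 against 3 cannot go below 0.1. The genotype itself stays open too and was not tested apart from it.

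Higher TE of 9 lists in untransformed heterozygous cultures may come from unequal spread of the arrays. After quantile normalization within each fraction 1 of the 9 lists, cholesterol synthesis, was still called, but the other 8 kept their direction and a median of 65.9% of their difference (other TOP mRNAs, for example, 0.28 ± 0.28 before and 0.18 ± 0.21 after, SE of list means), so this stays open. Without the 2 weak arrays 5 of the 9 lists were still called at the preset correlation, RAS-ERK output among them at a camera adjusted p of 0.0446. That fit also left out transformed WT embryo 3, which changes the shared spread. Without WT embryo 1 alone RAS-ERK output lost the call. Cholesterol synthesis, matrix, contractile genes and histones kept it in both removals, which argues against the weak array of untransformed WT embryo 1 as the sole source of these calls. For the other lists the weak array stays open. For cholesterol synthesis a genotype effect on translation stays open as a hypothesis, with an exact permutation p of 0.2 for the list mean (-4.35 ± 0.24 in WT, -4.09 ± 0.14 in heterozygous cultures, SD, n = 3).

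Most TE calls on transformation ran against the change in total RNA, and a polysomal signal at background could account for part of them. Of the called genes 45.2% in WT and 45.5% in heterozygous cells had polysomal means at or below the highest background value in both states, against 14.5% and 15.9% of all tested genes, which leaves the explanation open. Polysomal RNA held steady while total RNA changed stays open too. Genes bright in polysomal RNA and called in total RNA had a slope of polysomal on total change of 1.07 ± 0.10 (SD, 6 embryos), but held only 5 of the 104 and 3 of the 44 called genes, so the slope says nothing about the calls. Buffering and background cannot be told apart for the called genes.

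Other splits of the samples were counted for each comparison, but 3 against 3 allow only 10 splits and 3 embryo pairs only 4, too few for a share under 0.05. In total RNA of transformed cells the genotype split called 7 genes and the highest other split 138, with 3 of 10 splits as large. The genotype split thus did not give the highest count, and what set the other split apart was not tested. For transformation in total RNA the real counts were 2476 in WT and 2115 in heterozygous cells, the highest other was 0 in each, and 1 of 4 splits was as large. For transformation in TE the real counts were 104 and 44, the highest others 266 and 0, with 2 and 1 of 4 splits as large. In WT cells the real split therefore did not give the highest count either. The other genotype comparisons and both interactions had real counts of 0, so all 10 splits were as large, with 1 call as the highest other for polysomal RNA in transformed cells and for the TE interaction and 0 elsewhere.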

How the results depend on the processing

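Leaving out the 2 weak polysomal arrays, testing only genes bright in polysomal RNA and repeating the list tests under other settings or without an embryo were chosen after the data were seen; the other alternatives were planned. Calls for the genotype effect on TE stayed at 0 in both states under each alternative run, as did total and polysomal RNA of untransformed cells and both interactions. Eif4e in total RNA stayed lower in heterozygous cells under each setting run. Genotype numbers did not pair the samples throughout. In total RNA, WT and heterozygous cultures with the same number correlated at 0.484, -0.077 and 0.094 untransformed and at 0.347, -0.017 and -0.326 transformed. In each state 1 of 3 correlated best with its own number. Cultures of number 1 were thus alike in both states, and the reason was not tested. The replicate block is therefore given here only: with it, total RNA of transformed cells had 0 calls. The polysomal signal over background limited TE: background values there ranged from 1.96 to 3.30 with a median of 2.6.

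For the genotype effect in total RNA of transformed cells, 7 calls became 16 after quantile normalization, 13 after median centring, 16 with array weights and 0 with only the cultures of that state, and 0 to 51 when leaving out an embryo; the cause was not tested. The last 2 designs use fewer samples. For polysomal RNA of transformed cells 0 became 1 after quantile normalization, 2 with trend and robust settings, 2 with array weights and 0 to 1 when leaving out an embryo. For transformation in total RNA the WT count ranged from 952 to 2382 and the heterozygous count from 326 to 2561 when leaving out an embryo, and array weights gave 3255 in heterozygous cells.

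For TE on transformation, 104 calls in WT cells became 161 after quantile normalization, 160 after median centring, 513 with array weights, 188 with no replicate block, 0 with the total value as a covariate, 0 among genes bright in polysomal RNA and 65 without the 2 weak polysomal arrays. The 44 calls in heterozygous cells became 131, 110, 374, 156, 0, 4 and 688, and 82 with trend and robust settings. Leaving out an embryo gave 14 to 881 in WT and 0 to 540 in heterozygous cells. Removing an embryo of the other genotype leaves the change itself as it was, so it acts only through the shared spread and its degrees of freedom. For embryos of the same genotype the cause was not tested. Across all 12 comparisons 93 lists were called with camera at the preset correlation, 0 with an estimated correlation, 20 with fry, 81 after quantile normalization and 103 without the weak arrays. These are net counts that include lists newly called under a setting. The count without the weak arrays includes TE on transformation of WT cells and the TE interaction, where the WT change then came from WT embryo 2 alone. Leaving out polysomal arrays does not change the total RNA lists.

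Among named genes, reversed directions concerned TE values only. Lists turned direction without an embryo in TE and also in total RNA (ATF4 in untransformed cells without Het 3, adjusted p = 0.241; G2 and mitosis on transformation of WT cells without WT 2, 0.999) and in polysomal RNA (MYC ribosome biogenesis in transformed cells without WT 3, 0.317, and without the weak arrays, 0.621). With the total value as a covariate, transformation in WT cells gave -0.46 for Eif4e, -1.32 for Ptprz1, -0.87 for Epha3, -0.13 for Lyz2, -0.16 for Il6 and 0.81 for Cnn1. In heterozygous cells it gave -0.04 for Eif4e, -1.70 for Ptprz1, -0.73 for Zdbf2, -0.90 for Epha3 and -0.68 for Flt1. Where total RNA changed strongly, such estimates carry the error of the fitted slope. The Eif4e TE difference in transformed cells was -0.019 without the 2 weak polysomal arrays and -0.115 to 0.251 when leaving out an embryo, reversed without WT 1 (-0.102), WT 3 (-0.019), Het 1 (-0.012) and Het 3 (-0.115). Its interaction was 0.418 with the covariate and -0.201 to 0.211 when leaving out an embryo, reversed without WT 2 (0.211) and Het 2 (0.203). None of these passed the test. Named genes of total RNA reversed under no alternative run.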

Other observations

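The values here were set out after the results were seen, and no test was added. Replication-dependent histone mRNAs, which lack a poly(A) tail, were the list with the highest median relative TE in WT cells, though not the highest polysomal values. Transformation moved the list further in TE while total RNA changed little (mean change 0.07 ± 0.12 in WT and 0.05 ± 0.06 in heterozygous embryos, SD, n = 3). The TE mean of the list was -1.73 ± 0.16 in untransformed and -1.05 ± 0.20 in transformed WT cultures, and -1.52 ± 0.27 and -0.92 ± 0.14 in heterozygous cultures. Gas5, a noncoding TOP RNA, had a relative TE of 0.72 ± 0.22 in untransformed and 1.67 ± 0.18 in transformed WT cells.

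Endothelial and leukocyte transcripts had lower list means after transformation in all 6 embryos. The mean change of the leukocyte list was -0.61 ± 0.13 in WT and -0.70 ± 0.12 in heterozygous embryos, and of the endothelial list -0.55 ± 0.11 and -0.61 ± 0.14 (SD, n = 3), although the endothelial list was not called in total RNA (camera adjusted p = 0.13 and 0.0664).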
